A study of Mus musculus with 2 samples.

How the data were processed

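Acetylation of lysine 9 of histone H3 (H3K9ac), a mark of active promoters and enhancers, was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in hearts of mouse embryos at embryonic day 12.5. Per the labels, the hearts came from embryos of both sexes of strain B6NCrl and were sampled as 2 biological replicates of 1 group. A whole-heart sample holds cardiomyocytes together with endothelial, endocardial, epicardial, mesenchymal, neural crest and blood cells. The labels name no second condition, so no comparison between conditions was possible.

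The authors deposited 4 peak lists in the narrowPeak format, with coordinates of the mouse assembly mm10, per the text deposited with the samples. There was 1 list per replicate, 1 list called on both replicates together (the pooled list), and 1 list of replicated peaks derived from the other 3. That text names the alignments each list was derived from and further files of which it gives no description. The aligner, the peak caller, their versions, the filters, the control libraries behind each list and the rule that made the replicated list are not given in the sources used here. The fold enrichment of each peak is a ratio as the authors deposited it, and is the authors' own value for that peak. What it is relative to is not stated. It was used to describe, rank and filter peaks within a list, and values of the replicates are given side by side. The deposited −log10 p-values and −log10 q-values were taken as the authors wrote them, and the lowest −log10 p-value was just above 2 in every list (from 2.00 to 2.01). The deposited summit offset gave the position of each summit. The files give peaks and no read counts, so the depth of each library is unknown, and no statement about depth or undetected peaks could be tied to a number of reads. The number and covered length of the peaks per list are given in its place.

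Everything below was computed from those lists with scripts in Python. Versions were SciPy 1.17.1, NumPy 2.4.6, matplotlib 3.10.9 and Python 3.11.15. Genes and transcription start sites (TSSs) came from the GENCODE annotation release M21 of the same assembly. All peaks and genes lay within the lengths of the reference chromosomes. There were 21911 protein-coding genes on chromosomes 1 to 19, X and Y, counting each symbol 1 time. Peaks on other sequences were left out of gene counts.

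A protein-coding gene was called marked when a replicated peak touched the window of 1 kb on either side of any of its annotated TSSs. Its fold enrichment was that of the strongest such peak. Because any annotated TSS counted, the strongest peak could lie at a TSS inside the gene, as at Camk2a, Krt1, Ets1, Fhl2 and Myl1. Peaks of the replicates counted as shared when the overlap covered at least 50% of the length of either peak. Peaks not shared by even 1 base were called replicate-specific. Domains were made by merging replicated peaks at most 1 kb apart, and the widest 5% were called wide. A distal peak lay more than 2.5 kb from every annotated TSS, coding or not. It was tied to the protein-coding gene whose TSS was nearest to its summit, within 50 kb. CpG content was the observed over expected number of CpG dinucleotides within 500 bases on either side of the TSS of the longest transcript.

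Groups of genes were 25 lists fixed before the data were examined, among them markers of the cell types of the heart and of tissues that a dissection could carry along. The member Ahsp of the erythroid list had no protein-coding gene of that symbol and was left out. Shares of marked genes, of genes in wide domains and of genes with distal peaks were compared with those of all other protein-coding genes, or all other marked genes, by Fisher's exact test, two-sided. Median fold enrichments of marked genes were compared by a two-sided permutation test with 100000 random sets of marked genes of the same size. The last 3 comparisons took lists with at least 5 marked genes. The Benjamini-Hochberg adjustment ran over the lists of each comparison, with a threshold of 0.05. Genes are not independent replicates, so these tests describe the peak lists of these hearts and not the variation between hearts. Intervals of shares are Wilson 95% intervals and cover counting error only. Random placement of the replicated peaks on their own chromosomes, 100 times, gave the share expected at TSSs.

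The named genes were chosen by a rule fixed before the data were examined. It took the 10 protein-coding genes with the highest fold enrichment at a TSS, the genes with a TSS in the 10 widest domains, and the 10 genes tied to the most distal peaks. In each list it took up to 4 members with the highest fold enrichment, and the marked or unmarked members where these were 5 or fewer.

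The tests were tested on simulated data first. Among 40 simulated lists of 22 genes drawn from 21911, 20 had a share of 97% in place of 66%. Fisher's exact test recovered 20 of these 20 and called 0 of the 20 unchanged lists. With 20 lists raised by a fold of 2, the permutation test recovered 19, or 95% of them, and called 0 unchanged lists. Recovery of smaller differences, of lists of other sizes and at the base shares of wide domains and distal peaks was not simulated. Where only a covariate differed, the unmatched share test called 20 lists and the matched tests of shares and of medians called 0. The overlap code gave 0 mismatches with an exhaustive search over 400 simulated peaks.

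Alternatives fixed before the data were examined were the pooled list, each replicate alone, the stronger part of the lists by −log10 p, other overlaps, TSS distances, merging distances, width thresholds and reaches, 1 TSS per gene, a background without chemosensory receptors, and random sets matched in CpG content or in the length of the neighbourhood of the gene (10000 draws). Added after seeing the data were the replicated peaks that overlapped a peak of both replicates, a gene set without shared promoter regions, CpG matching for fold enrichment and matching in fold enrichment for domains. A permutation p against matched genes is two-sided and comes from these random draws of matched sets, in which no labels were permuted.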

Results

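H3K9ac was mapped in whole hearts of mouse embryos at day 12.5, when the heart already beats and its 4 chambers, valves and outflow tract are taking shape. The group held 2 biological replicates. Replicate 1 had 86547 peaks that covered 38.7 Mb, and replicate 2 had 94010 peaks that covered 43.8 Mb. The pooled list held 112688 peaks over 55 Mb, and the replicated list, used below unless another is named, held 47881 peaks over 39.9 Mb. Replicated peaks had a median width of 573 bp and a median fold enrichment of 4.11, with a highest value of 42.2. A q-value under 0.05 was recorded for 99.7% of them, against 88.7% of the peaks of replicate 1 and 88.0% of those of replicate 2. All positions are in mm10.

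The first comparison was between the replicates. Of the peaks of replicate 1, 48.3% (Wilson 95% interval 47.9 to 48.6) were shared with replicate 2, and 41.8% (41.5 to 42.2) of the peaks of replicate 2 were shared with replicate 1. The bases covered by both made up 45.7% of those covered by either. Sharing rose with the strength of the peak. In the lowest quartile of −log10 p, 20.4% of the peaks of replicate 1 and 13.7% of those of replicate 2 were shared, and in the highest quartile 97% and 94.0%. Across 39166 replicated peaks that had a peak in both replicates, the fold enrichment of the replicates correlated with Spearman's rho = 0.788 and, on the log2 scale, Pearson's r = 0.856. These are correlations across peaks, which are not independent replicates. The log2 difference between the replicates had an SD of 0.47, and a median of 0.09 with the higher values in replicate 2.

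**Figure D1:**
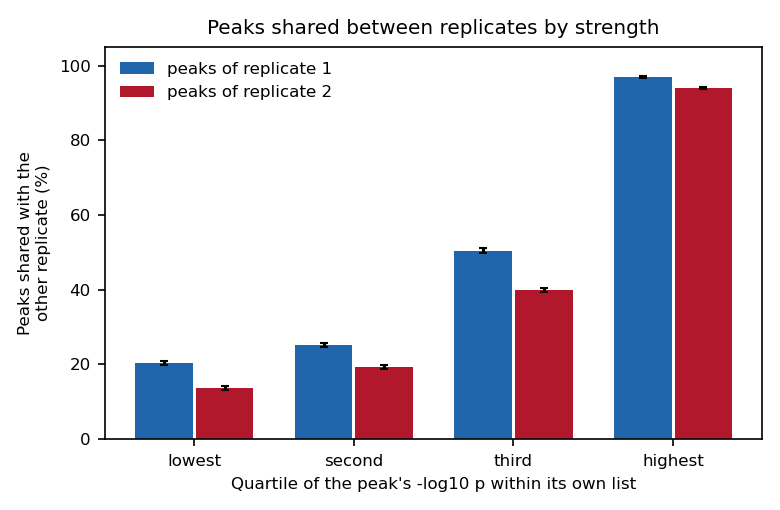
Share of the peaks of each replicate that were shared with the other replicate (vertical axis, percent), by quartile of the peak's −log10 p within its own list (horizontal axis). Bars are shares and error bars are Wilson 95% intervals. The share ran from 20.4% to 97% for replicate 1 and from 13.7% to 94.0% for replicate 2.

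Replicate-specific peaks were short, weak and mostly away from promoters. No peak of replicate 2 touched 40207 peaks of replicate 1 (46.5%), and no peak of replicate 1 touched 50239 peaks of replicate 2 (53.4%). Their median fold enrichment was 3.10 in replicate 1 and 3.04 in replicate 2, against 4.17 and 4.47 for the peaks that were touched. Within 1 kb of a TSS lay 15.9% and 16.4% of the replicate-specific peaks, against 56.6% and 56.2% of the touched ones. The replicated list was a subset of the pooled list, with the pooled fold enrichment for each peak. It held all 38939 pooled peaks that overlapped a peak of both replicates by 50% of either peak. A further 8942 of its peaks (18.7%) did not meet that overlap, and 371 touched a peak of neither replicate. The median fold enrichment was 4.73 for the 38939 peaks and 3.12 for the 8942 peaks.

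H3K9ac lay largely at promoters. Of 47874 replicated peaks on the main chromosomes, 24180 (50.5%, Wilson 95% interval 50.1 to 51) lay within 1 kb of an annotated TSS. Random placement of the same peaks gave 8.47% ± 0.12 (SD over 100 placements, highest 8.80). Peaks at a TSS had a median fold enrichment of 7.15 and a median width of 920 bp. Of the other peaks, 31.2% of the list had their summit in an intron, 13.6% between genes and 4.64% in an exon, with median fold enrichments of 3.4, 3.55 and 3.44. The TSS share depended on the list, with 31.2% in the pooled list, 37.7% in replicate 1 alone and 34.9% in replicate 2 alone. It was 75.6% in the stronger part of the replicated list.

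The 10 protein-coding genes with the highest promoter peaks had different functions, which were not tested as groups. The highest fold enrichment at a protein-coding TSS, 42.2, was at Smad7, an inhibitor of TGF-β and BMP signalling. The peak spanned positions 75367331 to 75376192 of chromosome 18, with its summit in a UTR exon and values of 34.4 in replicate 1 and 28.5 in replicate 2. Gata6, which encodes a cardiac GATA factor, followed with 41.4 (39.5 and 34.7 in replicates 1 and 2). In each replicate alone the value of Gata6 lay above that of Smad7. The peak of Gata6 covered 11049138 to 11057949 of chromosome 18, with the summit in a coding exon. Next came Nedd4 (39.6), which encodes a ubiquitin ligase, and Irf2bp2 (38), a transcriptional cofactor. Srf, the serum response factor that drives muscle genes, had 37.9 (28.8 and 36.6), at 46552957 to 46556224 of chromosome 17 with the summit in a coding exon. Mcl1, which protects cells from apoptosis, had 37.3, Hnrnpu, an RNA-binding protein gene, 35.8, and Cdk2ap1 35.6. The acetyltransferase gene Ep300 had 35.5 (28.7 and 36), and Slc25a3, the mitochondrial phosphate carrier gene, had 35.5 (22.6 and 34.6).

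Of 21911 protein-coding genes, 14424 (65.8%, Wilson 95% interval 65.2 to 66.5) were marked. In replicate 1 alone the share was 67.3% and in replicate 2 alone 68.0%. The replicates gave the same call for 95.4% of the genes, with 14318 marked in both, 421 in replicate 1 only and 591 in replicate 2 only.

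Genes of contraction and of cardiac identity were marked throughout. All 24 genes of the sarcomere and calcium handling list carried a peak (adjusted p = 0.00014, Fisher's exact test with Benjamini-Hochberg adjustment over 25 lists, against 65.8% of other genes). The strongest were Atp2a2, the calcium pump of the sarcoplasmic reticulum (26.0), and Tpm1, tropomyosin (25.8). Myom1 had 23.2 and Tnnc1 21.9, but the TSS of Myl12a lay within 1 kb of the peak of Myom1 and that of Nisch within 1 kb of the peak of Tnnc1. All 23 cardiac transcription factors were marked (adjusted exact p = 0.00021), led by Gata6, Srf, Hand2 (31.6) and Mef2a (28.0). All 20 cardiac ion channel and gap junction genes were marked (adjusted exact p = 0.00096). Among them were the connexin genes Gjc1 (22.0), Gja1 (18.7) and Gja5 (15.1), and Kcnh2 (20.4), which encodes a repolarising potassium channel. The peak of Gja5 lay within 1 kb of a TSS of Gpr89. Of 17 genes of perinatal and adult cardiomyocytes, 15 were marked, which did not pass the threshold (adjusted exact p = 0.093). Ckmt2 and Art1 were unmarked, and Fabp3 (14.0), Fhl2 (13.4), Hrc (12.1) and Pdk4 (11.9) were the strongest. The peaks of Fabp3 and Hrc lay within 1 kb of a TSS of another gene. Against genes matched in CpG content, the share of this list was higher, with an adjusted p of 0.00083 over 10000 matched draws.

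Each list of the other cell types of the heart was set against all other genes, and the lists were not compared with each other. In the endothelium and endocardium list, 23 of 24 genes were marked (adjusted exact p = 0.0015), with Npr3 (15.9), Ets1 (14.4), Fli1 (13.8) and Egfl7 (12.8) the strongest and Robo4 unmarked. The peak of Egfl7 lay within 1 kb of a TSS of Gm20532. Of the genes of cushion mesenchyme and matrix, which form the valve primordia, 20 of 21 were marked (adjusted exact p = 0.0037). Vim (20.5), Vcan (19.9), Fn1 (16.5) and Tgfb2 (15.7) led, and Dcn was unmarked. All 13 smooth muscle and pericyte genes were marked (adjusted exact p = 0.0094), with Mcam (16.9), Cspg4 (13.4), Smtn (12.4) and Notch3 (11.5) the strongest, and a TSS of Odf3l1 within 1 kb of the peak of Cspg4. That call was lost with a TSS distance of 0.5 kb (adjusted exact p = 0.059) and in the stronger part of the replicated list (adjusted p = 0.10). In the epicardium list, 12 of 17 genes were marked, which did not pass the threshold (adjusted exact p = 0.87) but did in the pooled list (adjusted p = 0.042). Tbx18 (12.8), Krt19 (10), Tcf21 (8.50) and Krt8 (8.14) carried peaks, while Upk1b, Upk3b, Msln, Muc16 and Gpm6a did not. Of the neural crest, glia and autonomic neuron list, 6 of 13 genes were marked (adjusted exact p = 0.19), including Ednrb (9.64), Erbb3 (7.91) and Phox2a (6.94). Mpz had 23.1, from a peak that is also that of Sdhc.

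Both blood cell lists had a lower share of marked genes than other genes in the replicated list. Of the macrophage and white blood cell list, 1 of 17 genes carried a peak, Spi1 (3.39; adjusted exact p = 4.9e-06). Of the erythroid list, 5 of 15 did (adjusted exact p = 0.017), namely Klf1 (9.49), Tal1 (7.71), Gypa (4.23), Slc4a1 (3.73) and Hba-x (2.58). The erythroid call was not reached in replicate 2 alone (adjusted exact p = 0.32) or in the pooled list (adjusted p = 0.29). Against CpG-matched genes the erythroid difference changed sign (adjusted permutation p = 0.50) and that of white blood cells missed the threshold (adjusted p = 0.14). Reads from the near-identical globin copies can be lost or split, so their values are uncertain.

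In the 5 fixed lists of genes for protein synthesis, metabolism and cell division, every member was marked. These were 30 cytosolic ribosomal protein genes (adjusted exact p = 4.9e-05), 25 respiratory chain genes (adjusted p = 0.00014), 21 genes of the citrate cycle and fatty acid oxidation (adjusted p = 0.00058), 18 glycolytic genes (adjusted p = 0.0014) and 25 cell cycle genes (adjusted p = 0.00014). Against genes matched in CpG content, of which 93.0% to 95.4% were marked, the calls of the ribosomal, respiratory, citrate cycle and cell cycle lists were lost, with adjusted p from 0.17 to 0.61. Outside the fixed lists some genes of this kind were unmarked, since 46 of 54 genes with the symbol stem Rpl, 42 of 44 with Rps and 25 of 27 with Cox were marked. The glycolytic call held against CpG-matched genes (adjusted permutation p = 0.0014).

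Genes of the liver, skeletal muscle and germline and chemosensory receptor genes were mostly unmarked. Of 22 liver genes, 5 carried a peak (adjusted exact p = 0.00014), namely Foxa3 (15.9), Apoa1 (5.22), Foxa1 (3.61), Trf (3.22) and Foxa2 (3.10). At Apoa1 neither replicate list had a peak in the TSS window, and the summit lay 1520 bp from the TSS. The peak of Trf lay within 1 kb of a TSS of Gm20425. The peak of Foxa3 had its summit outside the gene and within 1 kb of the TSS of Sympk. Of 22 skeletal muscle genes, 7 were marked (adjusted exact p = 0.0021), the strongest being Mylpf (24.3), Actn3 (12.5), Tnni2 (4.70) and Myl1 (4.46). The peaks of Mylpf and Actn3 lay within 1 kb of a TSS of Tbc1d10b and Zdhhc24. Against CpG-matched genes, the liver list (adjusted permutation p = 0.074) and the skeletal muscle list (adjusted p = 0.26) missed the threshold. In the germline list 3 of 18 genes were marked (adjusted exact p = 0.00013), Gdf9 (16.6), Zpbp (10.1) and Dazl (5.27). The peaks of Gdf9 and Zpbp lay within 1 kb of a TSS of Uqcrq and Spata48. Of 1497 chemosensory receptor genes, 2 were marked (0.134%, Wilson 95% interval 0.0366 to 0.486). These were Vmn1r4 (15.3), with its summit outside the gene and near the TSS of Nt5c3, and Olfr94 (4.25). In the epidermis list 9 of 17 were marked (adjusted exact p = 0.37), among them Grhl1 (8.04), Krt10 (7.70), Krt1 (7.09) and Ppl (4.78). The peak of Krt1, at 101845724 to 101846573 of chromosome 15, lay near a TSS inside the gene, whose 5′ end is at 101850794.

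Homeobox genes of the posterior trunk were mostly unmarked. Of the Hox genes of paralog groups 9 to 13, which pattern the posterior trunk and limbs, 2 of 16 were marked (adjusted exact p = 0.00010). These were Hoxd9 (3.55) and Hoxd13 (2.83). Of paralog groups 1 to 5, 10 of 15 were marked (adjusted exact p = 1.0), with Hoxb2 (10.3), Hoxa1 (9.62), Hoxa4 (4.86) and Hoxb4 (4.13) the strongest and Hoxa3, Hoxb1, Hoxb5, Hoxc4 and Hoxc5 unmarked. The difference between the anterior and posterior groups was not tested. Of 24 neural transcription factors, 17 were marked (adjusted exact p = 0.76), led by Dlx5 (8.29), Lhx2 (7.13), En1 (4.42) and Emx1 (4.37). Against CpG-matched genes, of which 96.0% were marked, this share was lower, with an adjusted p of 0.00083. In the stronger part of the replicated list the shares of neural transcription factors (adjusted exact p = 0.00080) and of anterior Hox genes (adjusted p = 0.041) lay below those of other genes. Of 22 genes of neuron differentiation, 15 were marked (adjusted exact p = 1.0), with Camk2a (11.9), Elavl4 (9.90), Slc17a7 (7.4) and Map2 (7.02) the strongest. The peak of Camk2a, at 60963544 to 60965354 of chromosome 18, lay at a TSS inside the gene, whose 5′ end is at 60925618.

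**Figure D2:**
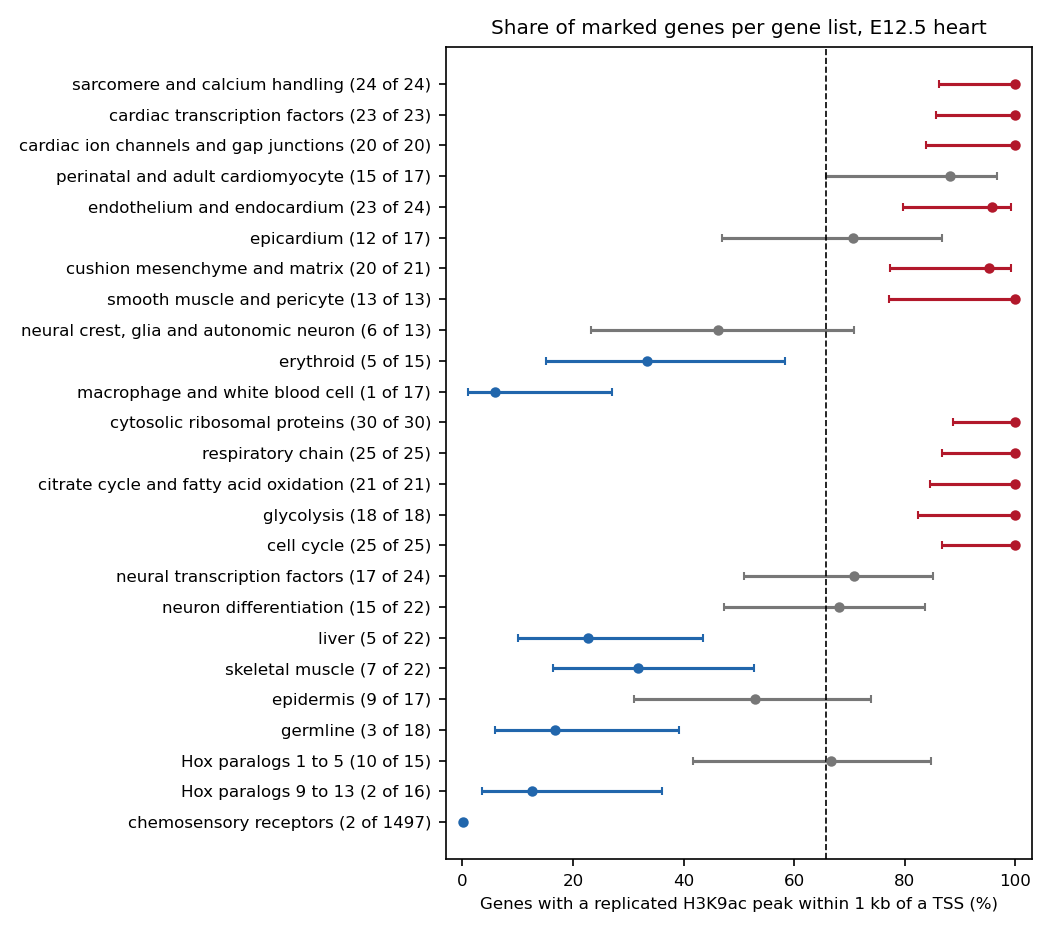
Share of genes with a replicated H3K9ac peak within 1 kb of a TSS (horizontal axis, percent) for each of the 25 gene lists (vertical axis, with marked and total genes). Points are shares, bars Wilson 95% intervals, and the dashed line is all protein-coding genes (65.8%). Red and blue mark lists above and below other genes at an adjusted p under 0.05, and grey the rest, so that 11 lists lie above and 7 below.

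Promoter peaks of some lists were higher, and those of others lower, than the peaks of other marked genes. The median over all marked genes was 11.9. Ribosomal protein genes had a median fold enrichment of 21.5, which was 1.81 times that of other marked genes, the highest ratio of any list (adjusted p = 0.00021, permutation test). Against CpG-matched marked genes the order differed, with ratios of 1.83 for sarcomere genes, 1.70 for glycolysis and 1.59 for ribosomal proteins (adjusted permutation p = 0.00070 for each). Their strongest members were Rps6 (35.1), Rpl10a (33.5), Rps8 (28.2) and Rpl8 (26.8). Glycolytic genes had 18.3 (1.54 times, adjusted permutation p = 0.0021), led by Ldha (28.5), Pgam1 (28.0), Eno1 (24.9) and Gapdh (22.5). Respiratory chain genes had 16.8 (1.42 times, adjusted permutation p = 0.0053), led by Uqcrfs1 (28.0), Cox4i1 (25.2), Cyc1 (23.4) and Sdhc (23.1). Cardiac transcription factors had a median of 15.9 (1.34 times, adjusted permutation p = 0.024) and sarcomere genes 15.3 (1.29 times, adjusted p = 0.040). The call of the transcription factors was lost in replicate 1 alone (1.30 times, adjusted permutation p = 0.059) and with −log10 p in place of the fold (adjusted p = 0.092). The citrate cycle and fatty acid oxidation list (1.21 times, adjusted permutation p = 0.17) was led by Etfa (22.7), Mdh2 (20.3), Acadl (19.0) and Idh3b (18.2). The cell cycle list (1.15 times, adjusted permutation p = 0.30) was led by Aurka (21.2), Ccnd2 (18.6), Ccna2 (18.2) and Ccnb1 (17.9). Neither list passed the threshold. The peaks of Cox4i1, Sdhc, Mdh2 and Aurka lay within 1 kb of a TSS of Emc8, Mpz, Styxl1 and Cstf1.

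Low median peaks were found in the neural, anterior Hox, liver, epidermis, skeletal muscle and erythroid lists. The 17 marked neural transcription factors had a median of 3.97, or 0.334 times that of other marked genes (adjusted permutation p = 0.00021). The 15 genes of neuron differentiation had 4.25 (0.357 times, adjusted permutation p = 0.00063). The 10 anterior Hox genes had 3.78 (0.318 times, adjusted permutation p = 0.00056), the 5 liver genes 3.61 (0.304 times, adjusted p = 0.0053), the 9 epidermal genes 4.67 (0.393 times, adjusted p = 0.0053), the 7 skeletal muscle genes 4.46 (0.376 times, adjusted p = 0.010) and the 5 erythroid genes 4.23 (0.356 times, adjusted p = 0.017). In replicate 1 alone the liver and erythroid calls were lost (adjusted permutation p = 0.079 for both). Within the heart, lower medians were found for perinatal and adult cardiomyocyte genes (6.76, 0.569 times, adjusted permutation p = 0.018), smooth muscle and pericyte genes (7.06, 0.595 times, adjusted p = 0.037) and endothelial and endocardial genes (7.97, 0.671 times, adjusted p = 0.029). The smooth muscle call was lost in either replicate alone, and these 3 calls, with those of erythroid and skeletal muscle genes, were lost against CpG-matched genes. The ion channel, cushion, epicardium and neural crest lists did not pass the threshold, with ratios from 0.625 to 0.95.

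**Figure D3:**
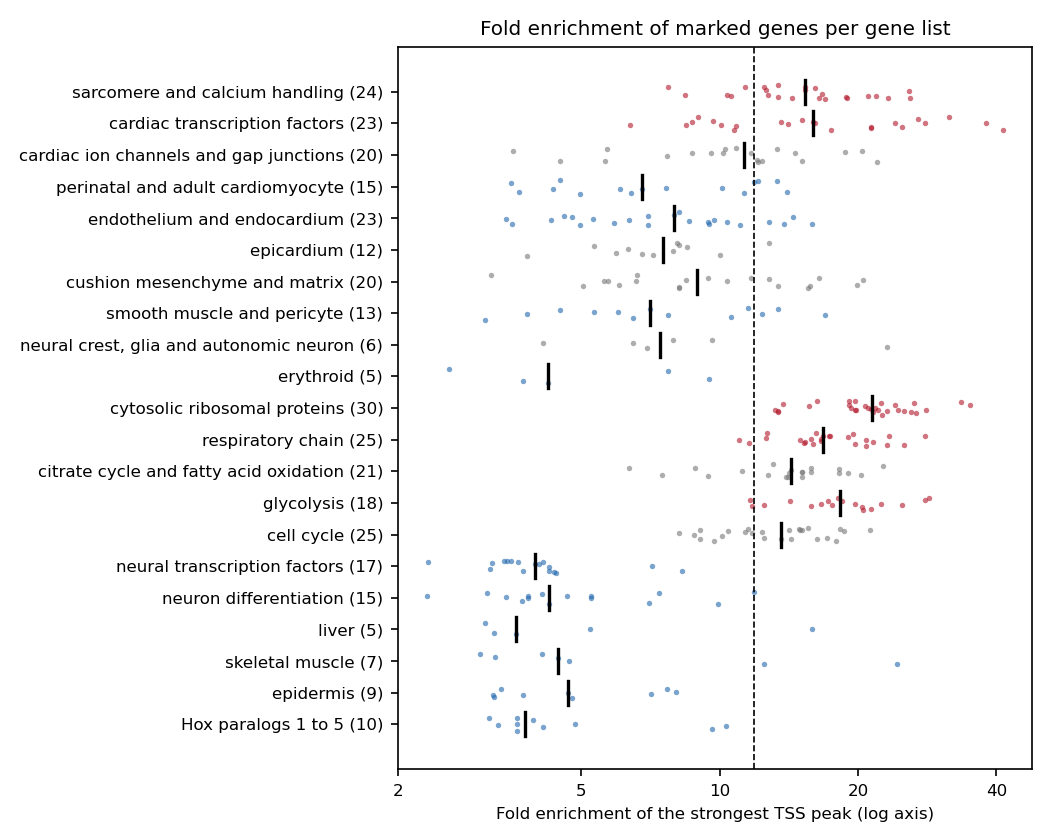
Fold enrichment of the strongest TSS peak (horizontal axis, ratio, log axis) of each marked gene, for the 21 lists with at least 5 marked genes (vertical axis, with the number of marked genes). Points are genes, black bars list medians, and the dashed line is the median of all marked genes (11.9). Red and blue mark medians above and below other marked genes at an adjusted p under 0.05, and ribosomal protein genes (21.5) and liver genes (3.61) have the highest and lowest medians.

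Wide domains were most frequent at sarcomere genes and cardiac transcription factors. Merging gave 32705 domains with a median width of 878 bp, and the widest 5% were at least 3886 bp wide. Of all marked genes, 11.2% had a TSS in such a domain. Among the sarcomere and calcium handling genes it was 22 of 24 (91.7%, adjusted p = 4.6e-18, Fisher's exact test), and among cardiac transcription factors 18 of 23 (78.3%, adjusted p = 1.4e-12). The share was 12 of 18 for glycolysis (adjusted exact p = 2.5e-07), 12 of 23 for endothelium and endocardium (adjusted p = 7.8e-06), 10 of 20 for cushion mesenchyme (adjusted p = 7.9e-05), 8 of 20 for ion channels (adjusted p = 0.0030) and 9 of 30 for ribosomal proteins (adjusted p = 0.013). The ion channel call was lost with peaks merged up to 3 kb apart (adjusted exact p = 0.38), and the ribosomal call against genes matched in fold enrichment (adjusted permutation p = 0.86). No respiratory chain gene lay in a wide domain (0 of 25, adjusted exact p = 0.27), although their promoter peaks were high. Even this lowest possible count had an unadjusted exact p of 0.10, so the test could not call lists of up to 25 marked genes below. Against genes matched in fold enrichment, of which 19.1% lay in wide domains, the respiratory share was lower (adjusted permutation p = 0.029). Of the other heart lists, epicardium (1 of 12), perinatal and adult cardiomyocyte (2 of 15) and smooth muscle (3 of 13) did not pass (adjusted exact p from 0.40 to 1.0). Cell cycle genes (5 of 25, adjusted exact p = 0.40) did not pass in the replicated list but did in replicate 1 alone (adjusted p = 0.00027) and replicate 2 alone (adjusted p = 0.0036). In those 2 lists wide meant the widest 5% of the list's own domains and not 3886 bp. Their peaks were narrower, with median widths of 252 and 263 bp against 573 bp in the replicated list, so the calls are not of the same widths. The remaining 9 lists did not pass, and at their sizes a lower share could not have been called.

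The widest domain, 36.2 kb at 60796284 to 60832476 of chromosome 10, held the TSS of Unc5b, a netrin receptor gene expressed in vessels. The second, 30.5 kb at 63227825 to 63258330 of chromosome 14, held that of Gata4, and the fourth, 25 kb at 57311982 to 57337015 of chromosome 8, held those of Hand2 and the non-coding gene Hand2os1. Gata4 and Hand2 encode transcription factors needed for heart formation. The third, 26.4 kb at 63955911 to 63982301 of chromosome 9, held no annotated TSS, and the nearest protein-coding TSS, that of Smad6, was 34686 bp away. Domains at Bahcc1 (23.1 kb, chromosome 11), at Midn and Cirbp (21.5 kb, chromosome 10), at Bcl9l (19.7 kb, chromosome 9) and at Gse1 (19.0 kb, chromosome 8) were also among the 10 widest. The genes of both myosin heavy chains of cardiac muscle lay in adjacent wide domains of chromosome 14. The domain of 20.5 kb at 54977821 to 54998362 held the upstream TSS of Myh7, and the domain of 20.0 kb at 54956369 to 54976407 held TSSs of Myh6, of another Myh7 transcript and of the non-coding genes Mhrt and Mir208b. The TSS peak of Myh7 had a fold enrichment of 18.8 (17.3 and 15.9 in replicates 1 and 2) and that of Myh6 12.8 (14.4 and 12.2), each with the summit in an intron.

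**Figure D4:**
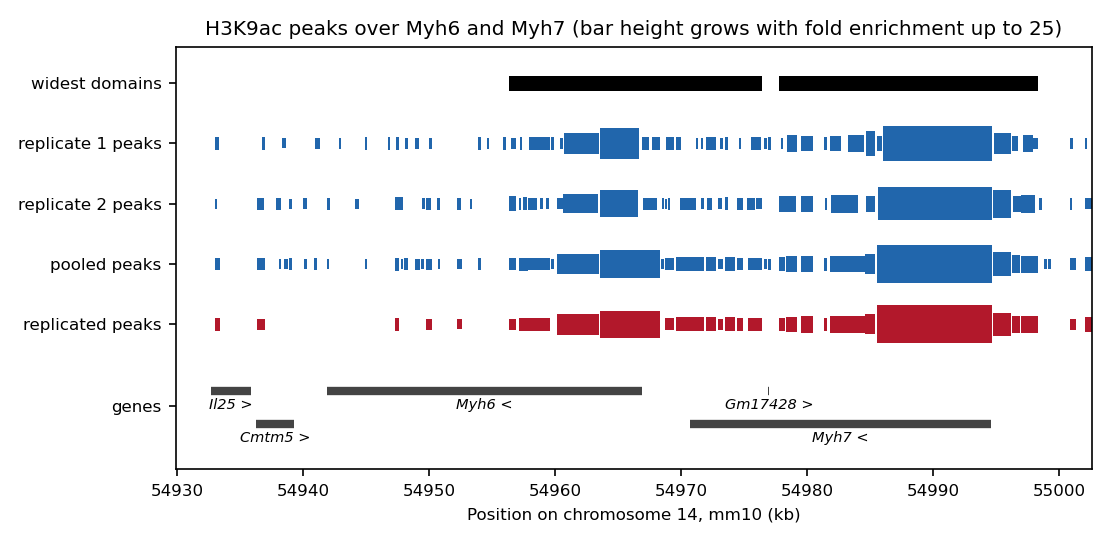
Peaks over Myh6 and Myh7 on chromosome 14 of mm10 (horizontal axis, kb) in the lists of replicate 1, replicate 2, the pooled list and the replicated list (rows), with protein-coding genes below and the domains that rank among the 10 widest above. Bars are peaks, their height grows with fold enrichment, and arrows give the strand. The 2 domains, 20.0 kb and 20.5 kb wide, lie next to each other with a gap in the 3′ part of Myh7, and both replicates have peaks across them.

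Distal peaks were most frequent at cardiac transcription factors and sarcomere genes. Distal peaks inside a gene's own wide domain were counted too, so this measure is not independent of domain width. There were 18505 distal peaks (38.7% of the list), of which 15694 were tied to a gene. At least 1 was tied to 34.5% of the marked genes and to 9.38% of the unmarked ones. Among marked list members it was 20 of 23 cardiac transcription factors (adjusted p = 6.2e-06, Fisher's exact test) and 20 of 24 sarcomere and calcium handling genes (adjusted p = 1.2e-05). Ion channels and cushion mesenchyme each had 14 of 20 (adjusted exact p = 0.0078 for both), glycolysis 12 of 18 (adjusted p = 0.024) and endothelium and endocardium 14 of 23 (adjusted p = 0.047). The last 4 calls were less firm. Only 2 lists passed in replicate 2 alone and 3 in replicate 1 alone. Against genes with neighbourhoods of matched length, cardiac transcription factors and sarcomere genes (adjusted p = 0.0021 for both) and glycolysis passed (adjusted permutation p = 0.016) and ion channels, cushion mesenchyme and endothelium did not (adjusted p from 0.11 to 0.22). Perinatal and adult cardiomyocyte genes (7 of 15), epicardium (6 of 12) and smooth muscle (6 of 13) did not pass (adjusted exact p = 0.58 for each). The other 12 lists did not pass either, among them epidermis with 5 of 9 and respiratory chain genes with 3 of 25 (adjusted exact p = 0.057).

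The genes tied to the most distal peaks were Casz1, a zinc finger factor of heart development, with 61, and Zmiz1 with 58. They were followed by Mical2 (51), Gse1 (50), Dab2ip (49), Tns1 (47), Sh3pxd2a (43), Tspan9 (41), Lrrfip1 (38) and Bahcc1 (37). These counts were not adjusted for the length of the gene or of its neighbourhood. All 10 genes were marked at a TSS, with fold enrichments from 13.1 at Sh3pxd2a to 21.5 at Lrrfip1.

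**Figure D5:**
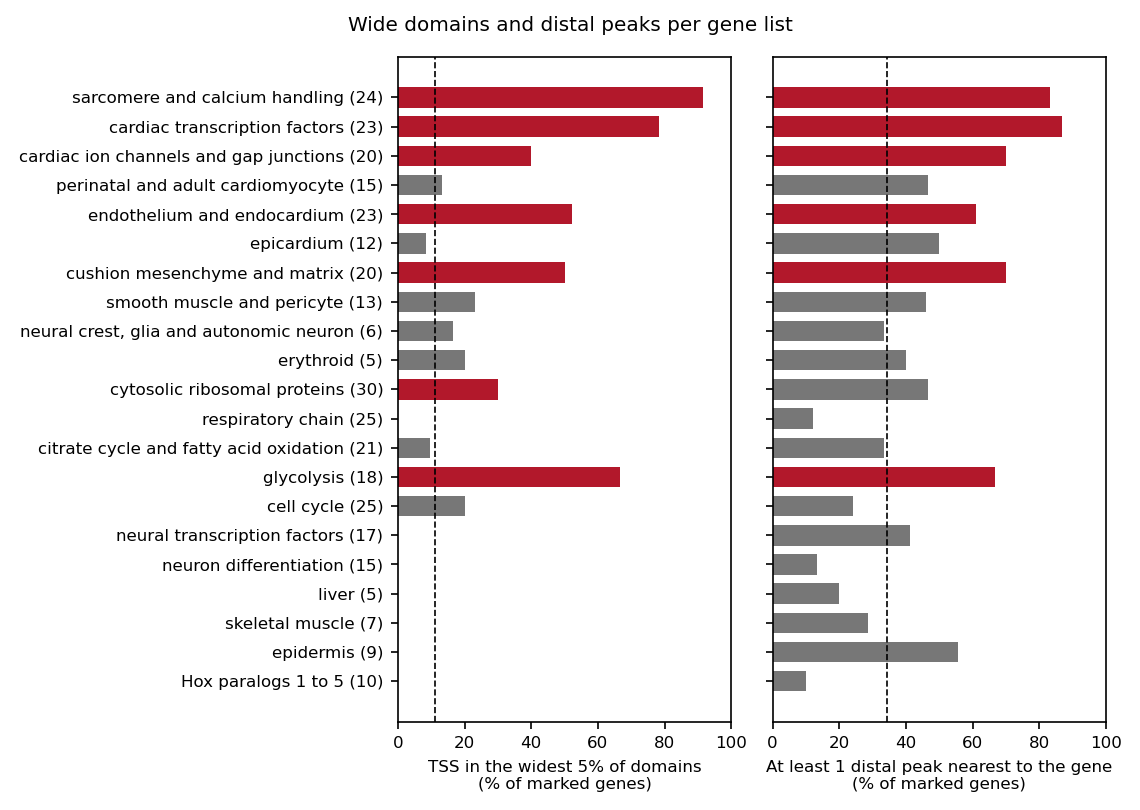
Share of marked genes with a TSS in the widest 5% of domains (left, percent) and with at least 1 distal peak tied to them (right, percent) for 21 gene lists (vertical axis, with the number of marked genes). Bars are shares, dashed lines are all marked genes (11.2% and 34.5%), red marks lists above other marked genes at an adjusted p under 0.05 and grey the rest. Sarcomere genes (91.7% and 83.3%) and cardiac transcription factors (78.3% and 87.0%) stand highest in both.

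The X chromosome carried fewer marked genes than the autosomes, and the Y chromosome almost none. On the X chromosome 447 of 948 protein-coding genes were marked (47.2%, Wilson 95% interval 44.0 to 50.3), against 67.3% of 20780 autosomal genes (adjusted p = 1.7e-35, Fisher's exact test). On the Y chromosome it was 2 of 183 (1.09%, adjusted exact p = 1.3e-83), where most genes are near-identical copies to which reads are hard to assign. Among autosomes the share ran from 54.5% on chromosome 7 to 79.5% on chromosome 12.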

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

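Replicated peaks outside the main chromosomes were part of the peak counts, the comparison of replicates and the merging of domains. They entered no comparison of TSSs or genes. Their number lay above 3, which was set here as what a count of 0 allows. There were 7 such peaks on 3 unplaced or unlocalised sequences, all 7 overlapping a peak of both replicates, with fold enrichments from 1.74 to 7.48. No explanation was tested.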

How the results depend on the processing

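Tests on replicated peaks that overlap both replicates, without shared promoter regions, with CpG-matched fold enrichment and with fold-matched domains were chosen after seeing the data. Values for lists are percentage points against other genes, or ratios of median fold enrichment, and the cause of a change was not tested unless stated. The X and Y calls kept their direction and their side of the threshold in all 8 alternatives. Of the alternatives over all lists, 236 of 275 for list marking, 106 of 125 for peak height, 136 of 167 for wide domains and 114 of 146 for distal peaks kept both. Many of the changes of sign below are of lists that passed the threshold in no setting.

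Peaks of replicates 1 and 2 were shared at 53.5% and 46.6% with any overlap of 1 base, 33.5% and 30.8% with 50% of both peaks, 66.6% and 56.3% with −log10 p of at least 5, and 66% and 57.2% in the stronger part of each list. The last 2 gave 58.2% and 58.3% of covered bases in common, and −log10 p of at least 5 left 30.7% and 41.0% untouched. In the stronger part of the replicated list rho was 0.806 and r 0.808, and r was 0.860 with an overlap of 50% of either peak. Peaks at a TSS and marked genes were 31.2% and 69.5% in the pooled list, 75.6% and 61.4% in the stronger part, 56.8% and 64.7% with peaks overlapping both replicates, 44.9% and 65.2% at 0.5 kb, 61.3% and 67.0% at 2.5 kb, and 40.1% and 62.6% with 1 TSS per gene. Without 1 replicate they ranged from 34.9% to 37.7% and from 67.3% to 68.0%.

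List marking changed most against CpG-matched genes, where by construction the comparison genes share CpG content. The lists above other genes went from 11 to 8 and those below from 7 to 4. Differences were 5.83 for ribosomal proteins, 5.05 for the respiratory chain, 6.97 for the citrate cycle, 4.63 for the cell cycle, -19.2 for liver, -19.0 for white blood cells and -13.8 for skeletal muscle, none past the threshold. Perinatal cardiomyocyte genes passed (44.6). Erythroid (9.57), epidermis (9.46), anterior Hox (-15.5) and neural transcription factors (-25.1, past the threshold) changed sign. Neural transcription factors also changed sign in the stronger part (-36.5, past the threshold), with peaks overlapping both replicates (-6.37) and with 1 TSS per gene (-8.40). Anterior Hox genes did so in the stronger part (-28.1, past the threshold), with peaks overlapping both replicates (-4.70), 1 TSS per gene (-2.56), 2.5 kb (-0.355) and no chemosensory background (-3.98). Genes of neuron differentiation did so in the stronger part (-20.5), at 0.5 kb (-1.52), with peaks overlapping both replicates (-1.06), 1 TSS per gene (-8.02), no chemosensory background (-2.47) and CpG matching (-11.2), and the neural crest list at 2.5 kb (2.21). Epicardium changed sign at 0.5 kb (-6.34) and with no chemosensory background (-0.0594), and passed in the pooled list (24.7). Perinatal genes passed in the pooled list (24.7) and at 2.5 kb (27.1). Smooth muscle was lost in the stronger part (23.2) and at 0.5 kb (27.2), the erythroid call in the pooled list (-16.1), and epidermis fell below in the stronger part (-32.0). Without 1 replicate, perinatal genes ranged from 20.2 to 26.9 and passed in replicate 1 alone, erythroid genes from -34.0 to -14.7 and anterior Hox genes from -7.27 to 12.

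For peak height, CpG matching left 5 of 10 lists below other genes and ended the calls of endothelium (0.787), erythroid (0.530), perinatal (0.926), skeletal muscle (0.581) and smooth muscle (0.874). Ion channels changed direction there (1.01). Cardiac transcription factors were lost with −log10 p (1.38). Epicardium passed with −log10 p (0.418), peaks overlapping both replicates (0.626) and the pooled list (0.572), where smooth muscle was lost (0.619). Without 1 replicate, ratios ranged from 1.30 to 1.39 for cardiac transcription factors, 0.535 to 0.661 for epicardium, 0.650 to 0.695 for smooth muscle, 0.347 to 0.467 for erythroid, 1.23 to 1.35 for the citrate cycle and 0.862 to 1.01 for ion channels. Epicardium and the citrate cycle passed in replicate 2 alone. Liver genes had 0.471 in replicate 1, and in replicate 2 alone too few were marked for a test.

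For wide domains, the width threshold was set anew for each peak list and merging distance. Ion channels were lost at a merging distance of 3 kb (9.56) and ribosomal proteins against fold-matched genes (6.72). Respiratory chain genes fell below those (-19.1, 1 list below in place of 0) and changed sign at 3 kb (5.55), in the pooled list (7.26) and in the widest 10% (1.62). Cell cycle genes passed in the widest 10% (33.7) and the pooled list (31.3), and neural transcription factors fell below there (-22.4 and -20.8, 1 list below in each). Lists that passed in no setting changed sign as follows: perinatal (-5.68), citrate cycle (1.95) and skeletal muscle (16.2) at 0.5 kb, epicardium (6.22), skeletal muscle (18.1) and epidermis (0.657) at 3 kb, neural crest (-5.72) and skeletal muscle (6.19) in the widest 10%, neural crest (-9.65) and epidermis (1.47) in the pooled list, neural crest with peaks overlapping both replicates (-9.82), and epicardium against fold-matched genes (3.50). Without 1 replicate, cell cycle genes ranged from 28.4 to 36.8 and passed in both, against 8.85 and no call in the main setting. The other ranges were respiratory genes from -3.27 to 0.328, perinatal genes from -0.519 to 7.001, neural crest from -5.39 to -4.99, erythroid from -7.18 to 0.732 and skeletal muscle from 5.33 to 9.31.

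For distal peaks, the lists above went from 6 to 2 in the pooled list and 2 to 3 without 1 replicate, and those below from 0 to 3 and 0 to 1. In the pooled list ion channels and cushion mesenchyme (13.3 each), endothelium (21.7) and glycolysis (27.2) were lost and anterior Hox genes fell below (-45.1). Matched neighbourhoods ended the calls of ion channels (25.4), cushion (24.9) and endothelium (19.5), and ribosomal proteins passed (24.8). Peaks overlapping both replicates ended cushion (24.2) and glycolysis (27.2). Respiratory genes fell below at 100 kb (-24.1, 1 list). Without 1 replicate, ion channels ranged from 16.9 to 18.5, endothelium from 16.9 to 30.5, cushion from 16.9 to 23.5, glycolysis from 19.6 to 26.8, perinatal genes from -0.301 to 8.51, neural crest from -1.02 to 29.2 and the citrate cycle from -24.9 to 5.36, while liver genes had 23.5 in replicate 1 alone, a change of sign. Other changes of sign were neural crest (3.52) and neural transcription factors (-0.400) at 20 kb, liver (3.94) at 100 kb, neural crest (27.2), erythroid (-11.7) and citrate cycle (4.97) in the pooled list, neural crest (4.90) and skeletal muscle (0.136) with peaks overlapping both replicates, and the citrate cycle with matched neighbourhoods (2.58). Read depth is unknown, so what it limits could not be assessed.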

Other observations

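The gene families and non-coding genes of the next paragraphs were chosen after their values were seen. Among 149 families of at least 15 protein-coding genes with a shared symbol stem, 69 had a higher and 39 a lower share of marked genes than other genes (adjusted p under 0.05, Fisher's exact test). The other genes included chemosensory receptors and genes with Gm or Rik names, which formed no family here. Among autosomal genes outside multicopy families and without Gm or Rik names, 82.4% were marked. Families were not compared with that share or with CpG-matched genes, so a higher share can reflect the background. All 20 semaphorin genes (Sema), 30 Mediator subunit genes (Med), 49 large mitochondrial ribosomal protein genes (Mrpl) and 35 vacuolar sorting genes (Vps) were marked. Of the zinc finger genes named Zfp, 341 of 394 (86.5%, adjusted exact p = 4.1e-19) were. None of the 22 β-protocadherin genes (Pcdhb, adjusted exact p = 6.2e-10) was, nor any of 57 keratin-associated protein genes (Krtap), 34 Rhox homeobox genes, 26 prolactin family genes (Prl) or 42 β-defensin genes (Defb). Of the cytochrome P450 genes (Cyp), 25 of 100 were. In wide domains, 4 of 123 families stood out. Klf genes had 8 of 16 marked members there (adjusted exact p = 0.0082), Bcl genes 9 of 17 (adjusted p = 0.0034), Zbtb genes 12 of 40 (adjusted p = 0.031) and histone genes (Hist) 16 of 59 (adjusted p = 0.023). Histone genes lie close together, so merging alone can widen their domains.

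Of 7074 long non-coding genes with no protein-coding TSS within 5 kb, 810 (11.5%, Wilson 95% interval 10.7 to 12.2) were marked, and 716 of these were marked in both replicates. The strongest was 1810026B05Rik on chromosome 7, with a fold enrichment of 41.5 (33.1 and 43.8 in replicates 1 and 2). The closest TSSs of this gene and of Chd2 were 5.04 kb apart. The peak itself lay 14827 bp from the nearest protein-coding TSS, that of Chd2. Mir17hg, the host of a microRNA cluster, had 31.7 and Malat1 31.2. Malat1 lay in a domain of 13.4 kb and Neat1 in one of 9.83 kb. The non-coding genes 5033428I22Rik and Gm34030 lay in the 25 kb domain of Hand2.

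The patterns and tests below were chosen after the main results were seen. For joined promoters and for random positions, values that bear on the outcome had been seen when the test was written. For the other tests the outcome that would count for or against each explanation was written before the test was run.

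Wide domains at sarcomere genes and cardiac transcription factors could be a by-product of high peaks, which merge more easily. Among marked genes matched in fold enrichment, however, 15.6% and 16.9% lay in wide domains, against 91.7% and 78.3% of the lists (the larger adjusted permutation p was 0.00084). Joined promoters of neighbouring protein-coding genes also fall short. Of the 40 list genes in wide domains, 5 (12.5%, Wilson 95% interval 5.46 to 26.1) shared the domain with a TSS of another protein-coding gene. The genes were Myh6, Myh7, Tnnc1, Myom1 and Tcap. TSSs of non-coding genes and further TSSs of the same gene were not counted, so joining with those was not tested. The cause stays open and the pattern was not confined to these lists, since glycolysis (66.7% against 20.2%), endothelium (52.2% against 5.83%), cushion mesenchyme (50% against 8.71%) and ion channels (40% against 10%) also lay above fold-matched genes, while perinatal and adult cardiomyocyte genes (2 of 15, adjusted permutation p = 0.72) did not pass.

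Neural transcription factors were marked in a heart, but weakly, with 0.315 times the median height of CpG-matched marked genes (permutation p = 0.00020, the smallest that 10000 draws can give), which argues against a weak mark of CpG-rich promoters in general. Of all 24 list genes, 17 were marked in replicate 1, 20 in replicate 2 and 14 in both. Over 10000 random placements of the peaks of each replicate, at most 6 were marked in both (permutation p = 0.00020, again the smallest possible). This argues only against positions spread at random along the chromosomes. Replicated peaks in general lay at a TSS more often than when placed at random (50.5% against 8.47%). The test therefore cannot tell weak marks from spurious calls at promoters. Independent calls at the rates of the replicates would give 14.2 genes in both, so chance may still decide which of these weak promoters pass in a replicate. Neural cells in the dissected hearts cannot be told apart from weak marks in heart cells, because the share of neuron differentiation genes did not pass the test against CpG-matched genes (68.2% against 79.4%, permutation p = 0.17). Low acetylation of silenced CpG-rich promoters, or a mark in few cells such as cardiac neural crest, may remain, and neither was tested. Weak marks were not confined to neural genes. Anterior Hox (0.321 times), liver (0.392) and epidermis (0.496) genes also lay below CpG-matched marked genes at an adjusted permutation p under 0.05. Erythroid (0.530) and skeletal muscle (0.581) genes did not pass.

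The lower share of marked genes on the X chromosome was set against gene content. Against CpG-matched autosomal genes the difference was -11.4 percentage points (47.2% against 58.5%, permutation p = 0.0002, the smallest that 10000 draws can give). Without multicopy families and genes with Gm or Rik names it was -14.6 (67.8% against 82.4%, p = 6.2e-16, Fisher's exact test). Neither property by itself accounts for all of the difference of about 20 points, but CpG content goes with a large part of it.

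Marked X-linked genes also had lower peaks than CpG-matched marked autosomal genes, with a median of 8.41 against 10.5, a ratio of 0.801 (permutation p = 0.0002, the smallest that the draws can give). The ratio was 0.813 in replicate 1 and 0.788 in replicate 2. Whether 1 active X chromosome per cell lowers the enrichment was not tested, because the ratio only measures the pattern itself. Other causes may lie behind it, and no sample of a single sex was analysed here.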
